A study of Homo sapiens with 6 samples.

How the data were processed

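RNA sequencing was performed on PC3 cells, an established human prostate cancer cell line. Per the labels, 3 libraries came from cells with control short hairpin RNA (shRNA) and 3 from cells with shRNA against VprBP, the protein encoded by DCAF1. Per the labels' protocols, libraries were built from total RNA with a SMARTer mRNA-seq kit. Whether reads were assigned by strand is not given in the sources used here. The labels number the samples sh1 to sh3 in each group and do not say whether a number stands for a hairpin, a culture or a repeat library. The p-values therefore measure only the spread between these samples, which may be technical.

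The values deposited by the authors are named raw counts, but they are a scaled signal: gene-level estimated read numbers multiplied by one step per library. This was read from the values. The 75th percentile over the listed genes lay between 78.99 and 79.02 in all 6 libraries, and low values were spaced by one step per library, equal to the value of 1 read. That step was between 0.0254 and 0.0439. Between 57.4% and 65.7% of the values of a library were whole multiples of its step, within 0.02 reads, so whole reads could not be recovered for every gene. Per the submitters' processing notes, Partek was used and the genome build was hg38. The aligner, quantifier, annotation release and scaling method are not given in the sources used here. The 12227 listed genes each reached at least 150 estimated reads in some library, so less abundant genes were not analysed here. Of the listed genes, 11219 were protein coding, 560 were long noncoding RNA genes and 448 had other types, and 20 symbols were listed more than once under different identifiers. Coordinates are those of the deposited table on hg38, with the end reduced by 1. This offset was checked against GENCODE 29: of 12012 genes found on the same chromosome, 6958 had an identical end after that step and 153 without it, and 6912 had an identical start.

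The depth, estimated as the sum of a library's values divided by its step, was 32293133, 22981877 and 23778390 reads in control replicates 1 to 3. It was 39633838, 31337898 and 23029450 reads in knockdown replicates 1 to 3. These sums cover listed genes only. Replicate pairs within a group differed by more than counting noise, with a chi-square per degree of freedom between 3.39 and 6.75. That test covers counting error alone: no pair matched as a library deposited again under another name would, but it cannot tell separate cultures from repeat libraries of one culture. The libraries were kept apart because the labels list them as separate samples.

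The planned test was a count model. Because the values are not counts, no count model was used, and genes were tested with limma 3.58.1 in R 4.3.3 on log2(value + 0.5), with a mean-dependent prior variance (trend) and all 6 libraries. No further filter on low values was applied. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 12227 genes, and a gene was called at an adjusted p under 0.05 with no fold minimum. Log2 fold changes and their standard errors (SE) are on the log2(value + 0.5) scale, which understates changes of low genes. Folds in the text are ratios of group means of the deposited values. Means are given ± SD over the 3 libraries of a group. The DCAF1 difference was also tested by an exact permutation test, two-sided, over the 20 assignments of the 6 libraries.

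Before the data were examined, 46 gene lists were fixed, and 42 had at least 5 listed members. These were tested with camera in limma, with a preset correlation between genes of 0.01 and again with a correlation estimated for each list, adjusted over the tested lists. Older symbols were matched through a gene name table. The rule for named genes was also fixed in advance. It takes DCAF1, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean value of at least 5 and groups that do not overlap, without clone-named genes. For each list it adds up to 3 called members in each direction with the largest absolute change and a mean of at least 1, and, for lists of other cell types, the most abundant member. A few genes selected by this rule are not reported here. The thresholds were written for CPM and were applied to the deposited values, which sum to about that scale.

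Genes that share sequence with close relatives are uncertain, because the authors' counting could split such reads between copies. Among named genes this concerns MT2A, UGT1A6, IFIT1, IFIT3, CXCL3, CXCL5, KRT17, KRT6B, KRT75, HSPA1B, MUC5AC, MUC5B, AKR1B10 and AKR1C2. Without a stated strand setting, overlapping genes on opposite strands cannot be told apart either.

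Alternatives were median-ratio and library-size scaling of the values, a mean of at least 5, limma-voom on the estimated reads, a replicate block, each library left out in turn, a test against a fold of 1.5 (treat), a 2-fold minimum, and an adjusted p under 0.01. Pseudocounts of 0.1 and 1 were added after the data had been seen. The procedure was tested on simulated data with the gene means, depths and spread of these libraries. Of 50 genes seeded at each size, 52% were recovered at 1.25-fold, 88% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, and 14 of 12027 unchanged genes were called. The 14 are a share of unchanged genes, not of calls. Most of the 12227 simulated genes were unchanged, whereas 60.9% of genes were called in the data. The p cutoff after adjustment was therefore stricter in the simulation, and these recoveries do not give the power in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.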

Results

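Transcript levels were measured by RNA sequencing in PC3 cells that carried control shRNA or shRNA against VprBP. VprBP, encoded by DCAF1, is a substrate receptor of the CRL4 ubiquitin ligase and has been described as a histone kinase. The series concerns inhibitors of this kinase activity and prostate tumour growth. Inhibitor-treated cells were not analysed here, and the question addressed is which transcripts differ when VprBP is depleted. Each group had 3 libraries, with 22981877 to 32293133 estimated reads per control library and 23029450 to 39633838 per knockdown library, and 12227 genes were listed. The median absolute difference between libraries over genes was 4.41% to 6.54% within groups and 14.9% to 16.8% between groups. Knockdown replicate 3 lay farthest from the other libraries of its group, with a chi-square per degree of freedom of 6.27 and 6.75 against them, compared with 3.39 to 3.85 for the remaining pairs within groups.

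DCAF1 was lower in every knockdown library than in every control library. Its value was 78.8 ± 0.465 (SD, n = 3) in control cells and 39.9 ± 1.36 (SD, n = 3) in knockdown cells, so that 50.6% of the control level remained. The 3 control libraries gave 79.4, 78.5 and 78.7, and the 3 knockdown libraries gave 38.5, 41.1 and 40.2. The log2 fold change was -0.97 (SE 0.05, limma adjusted p = 3.56e-11). The exact permutation test gave p = 0.1, which is the smallest p that 3 libraries against 3 allow. DCAF1 (ENSG00000145041.17) lies on the minus strand of chromosome 3 from 51395867 to 51500015 (hg38) and overlaps RBM15B on the opposite strand. RBM15B, named here because of the overlap, had values of 133 ± 5.15 and 131 ± 4.50 in control and knockdown cells (SD, n = 3 each; limma adjusted p = 0.796).

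Knockdown cells had far higher levels of interferon-stimulated transcripts and of IL6 and far lower levels of FCGBP and of the mucin genes MUC5B and MUC5AC than control cells. IL6, an inflammatory cytokine, had the largest increase among named genes, 35.9-fold, from 1.56 ± 0.259 to 55.9 ± 1.06 (SD, n = 3 each). The interferon-induced genes IFI6, IFI44 and MX1 rose 25.6-fold, 22.5-fold and 16.7-fold. MT2A, a metallothionein that binds zinc and copper, rose 17.3-fold, from 19.0 ± 0.666 to 329 ± 28.1 (SD, n = 3 each). Among genes with a mean value of at least 5, the 10 largest increases by log2 fold change also included OASL (13.8-fold), the keratin gene KRT17 (11.4-fold), DDX60 (9.75-fold), IFIT3 (9.65-fold) and IFIT1 (8.44-fold).

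Among the decreases, FCGBP, which encodes a mucus protein that binds the Fc part of IgG, fell from 177 ± 3.37 to 0.774 ± 0.210 (SD, n = 3 each), a 229-fold difference. The gel-forming mucin gene MUC5B was among the abundant transcripts of control cells and was 13.3-fold lower in knockdown cells, at 1049 ± 74.5 against 79.0 ± 10.6 (SD, n = 3 each). Its neighbour MUC5AC was 16.0-fold lower, at 146 ± 5.77 against 9.14 ± 0.432 (SD, n = 3 each). DMBT1, another secreted mucosal glycoprotein gene, was 16.9-fold lower. PPP1R1B, which encodes an inhibitor of protein phosphatase 1, was 25.6-fold lower, and the glucuronosyltransferase gene UGT1A6 was 33.5-fold lower. FAM131B (16.5-fold), MSMP (13.8-fold), the sterol transporter gene ABCG1 (12.1-fold) and STUM (10.7-fold) completed the 10 largest decreases by log2 fold change among genes with a mean value of at least 5.

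A call and groups that did not overlap were conditions for the choice of these 20 genes. Their limma adjusted p-values lay between 6.59e-18 for MT2A and 8.13e-11 for ABCG1. The log2 fold changes were 4.79 (SE 0.10) for IL6, 3.99 (SE 0.06) for MX1, 4.08 (SE 0.06) for MT2A, -7.14 (SE 0.11) for FCGBP, -3.93 (SE 0.06) for MUC5AC and -3.73 (SE 0.07) for MUC5B. On hg38, IL6 (ENSG00000136244.12) spans 22725884 to 22732002 of chromosome 7 and MX1 (ENSG00000157601.15) spans 41420020 to 41470071 of chromosome 21. FCGBP (ENSG00000275395.7) spans 39863323 to 39934626 of chromosome 19. MUC5AC (ENSG00000215182.8) spans 1157953 to 1201138 of chromosome 11, and MUC5B (ENSG00000117983.17) spans 1223066 to 1262172. UGT1A6 shares exons with the other genes of the UGT1A locus, so its reads cannot be assigned with certainty. IL6, MX1, IFIT1, IFIT3 and MUC5B overlap genes on the opposite strand, STEAP1B, TMPRSS2, LIPA and MUC5B-AS1 among them.

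**Figure D1:**
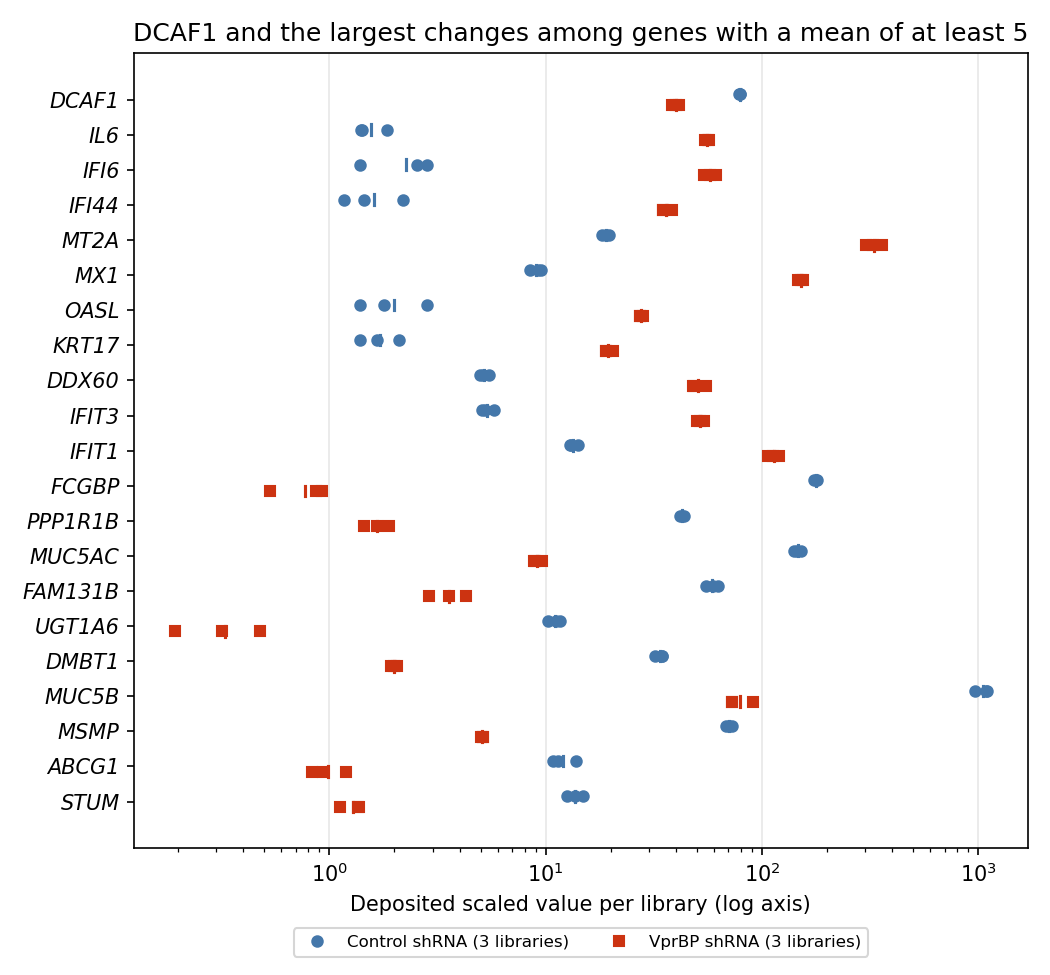
Deposited scaled value (log axis) of DCAF1 and of the 10 largest increases and 10 largest decreases in PC3 cells among genes with a mean value of at least 5 and groups that do not overlap. Circles are the 3 control libraries, squares the 3 VprBP shRNA libraries and short vertical lines the group means; FCGBP lies at 177 in control cells and at 0.774 in knockdown cells on average.

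Across the transcriptome, 7441 of 12227 genes (60.9%) were called, 4037 higher and 3404 lower in knockdown cells. Most differences were small. The median absolute log2 fold change of called genes was 0.33, and 6022 of them (80.9%) differed by less than 1.5-fold. At least 2-fold differences were called for 226 higher and 228 lower genes. The groups did not overlap for 7921 genes (64.8%), against 10% by chance for 3 libraries against 3.

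**Figure D2:**
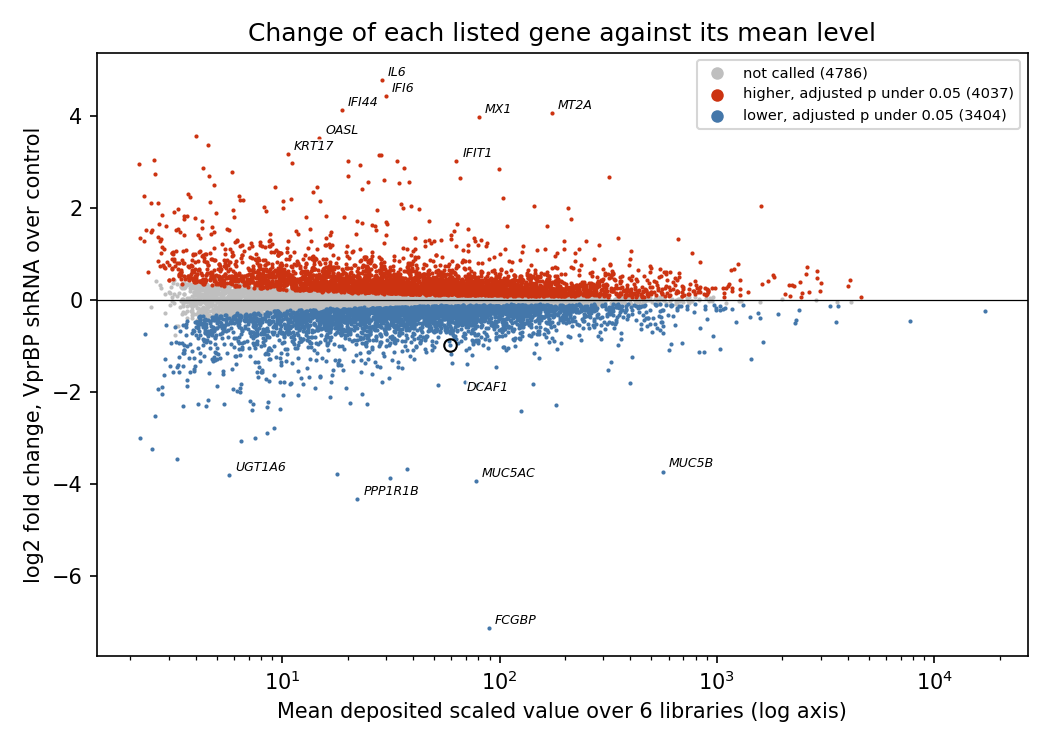
Log2 fold change of each of the 12227 listed genes (vertical axis, VprBP shRNA over control, 3 libraries each) against its mean deposited scaled value over 6 libraries (log axis). Red points are the 4037 genes called higher, blue points the 3404 called lower and grey points genes not called; the ring marks DCAF1 at -0.97, FCGBP lies lowest at -7.14 and IL6 highest at 4.79.

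Interferon-stimulated genes were higher without exception among those measured. All 36 listed members of this list rose, 32 of them at least 2-fold, with a median log2 fold change of 2.36 (camera adjusted p = 3.20e-26; adjusted p = 0.0216 with an estimated correlation). IFI6 rose from 2.26 ± 0.769 to 57.6 ± 3.81, IFI44 from 1.60 ± 0.535 to 36.0 ± 2.12, and MX1, which encodes an antiviral GTPase, from 9.05 ± 0.560 to 151 ± 3.90 (SD, n = 3 each). Of 30 NF-kB and inflammatory target genes, 22 rose, 2 fell and 6 were not called, with a median log2 fold change of 0.57 (camera adjusted p = 6.75e-08; adjusted p = 0.0386 with an estimated correlation). Next to IL6, the chemokine genes CXCL3 and CXCL5 rose 7.40-fold and 6.44-fold. NFKBIA, which encodes an inhibitor of NF-kB and is itself an NF-kB target, fell, from 274 ± 3.98 to 189 ± 2.43 (SD, n = 3 each), and TNFAIP2 was 1.16-fold lower. Of 13 antigen processing and presentation genes, 11 rose, none fell and 2 were not called (median log2 fold change 0.30, camera adjusted p = 0.00166). This call did not hold with an estimated correlation (adjusted p = 0.0992). The peptide transporter gene TAP1 rose 1.65-fold and the peptidase gene ERAP1 rose 1.56-fold.

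DNA replication genes rose together, by modest amounts. Of 47 genes of DNA replication and the G1/S transition, 39 rose, 1 fell and 7 were not called, and adjusted over the list alone 41 rose and 1 fell. The median log2 fold change was 0.32 (camera adjusted p = 7.64e-09; adjusted p = 0.0237 with an estimated correlation). CCNE2, which encodes cyclin E2, rose 4.99-fold, from 3.36 ± 0.337 to 16.8 ± 0.592, and RRM2, a ribonucleotide reductase subunit gene, rose 2.11-fold, from 259 ± 7.61 to 547 ± 19.0 (SD, n = 3 each). The thymidine kinase gene TK1 rose 1.63-fold, and the transcription factor gene E2F2 was 1.31-fold lower. Of 38 mitosis and G2/M genes, 30 rose, none fell and 8 were not called, and adjusted over the list alone 30 rose and 1 fell. Their median log2 fold change was 0.19 (camera adjusted p = 9.90e-06; adjusted p = 0.360 with an estimated correlation). UBE2C, AURKB and CDK1 rose 1.49-fold, 1.47-fold and 1.43-fold. Of 32 homologous recombination and Fanconi repair genes, 16 rose, 2 fell and 14 were not called (median log2 fold change 0.13, camera adjusted p = 0.0304; adjusted p = 0.650 with an estimated correlation). RAD51AP1 (1.58-fold), BRIP1 (1.56-fold) and FANCA (1.41-fold) rose most, and FANCE was 1.36-fold lower. Without knockdown replicate 3 the call of the homologous recombination and Fanconi repair list was lost, with an adjusted p of 0.0840, in a range from 0.0173 to 0.650 over the 15 alternatives.

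Genes that restrain growth moved in both directions. Of 8 cyclin-dependent kinase inhibitor genes, 3 rose, 3 fell and 2 were not called (camera adjusted p = 0.966). CDKN1A, which encodes p21, rose 3.21-fold, from 12.4 ± 0.338 to 39.7 ± 1.21, whereas CDKN2B, which encodes p15, was 2.58-fold lower, at 49.2 ± 2.79 against 19.1 ± 1.14 (SD, n = 3 each). CDKN2D and CDKN2C rose 1.68-fold and 1.67-fold, and CDKN1C and CDKN2A were 1.96-fold and 1.74-fold lower. Of 22 p53 target genes, 6 rose, 7 fell and 9 were not called (camera adjusted p = 0.871), with TP53I3 2.55-fold higher and BBC3, which encodes the pro-apoptotic protein PUMA, 2.52-fold lower. Among 27 growth-suppressing genes that are often silenced in cancer, 12 rose, 11 fell and 4 were not called (camera adjusted p = 0.959). THBS1, which encodes the anti-angiogenic protein thrombospondin 1, rose 4.16-fold, from 622 ± 19.3 to 2587 ± 41.8 (SD, n = 3 each), TNFAIP3 rose 3.23-fold and IGFBP3 rose 3.06-fold, while TIMP3 and SPRY1 were 2.61-fold and 2.26-fold lower. Of 24 pro-apoptotic genes, 10 rose, 5 fell and 9 were not called, 11 and 5 adjusted over the list alone (camera adjusted p = 0.482), with HTRA2, a mitochondrial protease gene, 1.22-fold lower. Of 13 anti-apoptotic genes, 6 rose, 5 fell and 2 were not called (camera adjusted p = 0.966), with BCL2A1 3.12-fold and BIRC3 2.23-fold higher and BAG3 1.51-fold lower.

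The ubiquitin ligase partners of VprBP and the chromatin enzymes examined showed no common direction. Of 25 CRL4 ubiquitin ligase components, 6 rose, 5 fell and 14 were not called, 6 and 4 adjusted over the list alone (camera adjusted p = 0.966). The receptor gene DDB2 rose 1.41-fold and DCAF10 was 1.46-fold lower. Of 25 Polycomb and DNA methylation enzyme genes, 6 rose, 8 fell and 11 were not called (camera adjusted p = 0.815). EZH2, which encodes the H3K27 methyltransferase of Polycomb complexes, rose 1.24-fold and BMI1 rose 1.45-fold, while the demethylase gene KDM6B and the chromodomain gene CBX7 were 1.85-fold and 1.83-fold lower. Of 12 replication-dependent histone genes, 2 rose, 4 fell and 6 were not called (camera adjusted p = 0.762), and H1-2 was 1.30-fold lower. Of 339 zinc finger genes with ZNF symbols, 82 rose, 72 fell and 185 were not called, 79 and 67 adjusted over the list alone (camera adjusted p = 0.966), with ZNF326 1.74-fold higher and ZNF467 3.34-fold lower.

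Mesenchymal genes were mostly higher. Of 21 listed members, 18 rose, 2 fell and 1 was not called, with a median log2 fold change of 0.63 (camera adjusted p = 2.17e-07; adjusted p = 0.0386 with an estimated correlation). TGFBI, an extracellular matrix protein gene induced by TGF-beta, rose 9.05-fold, from 3.99 ± 0.513 to 36.1 ± 3.80 (SD, n = 3 each), and VIM, which encodes vimentin, rose 4.06-fold from a control value of 16.7 ± 1.29 (SD, n = 3). S100A4 and the transcription factor gene SNAI1 were 1.69-fold and 1.59-fold lower. Of 30 epithelial genes, 11 rose, 11 fell and 8 were not called (camera adjusted p = 0.966), with KRT8 1.64-fold higher and the junction genes TJP3 and CLDN3 1.68-fold and 1.60-fold lower. Of 15 keratin genes, 8 rose, 2 fell and 5 were not called, 9 and 2 adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 0.00674; adjusted p = 0.447 with an estimated correlation). KRT75 and KRT6B rose 3.44-fold and 2.38-fold, and KRT37 was 6.11-fold lower. Of 19 YAP and TEAD target genes, 10 rose, 5 fell and 4 were not called, 10 and 6 adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 0.0218; adjusted p = 0.222 with an estimated correlation). CCN2 and CCN1, which encode matricellular proteins, rose 3.21-fold and 3.06-fold, and ARHGEF17 was 1.70-fold lower.

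Several groups tied to tissue identity and matrix split between higher and lower members. Of 16 TGF-beta and BMP target genes, 8 rose, 7 fell and 1 was not called (camera adjusted p = 0.661). PMEPA1 rose 4.20-fold, and the BMP-responsive genes SMAD6 and ID1 were 2.55-fold and 1.90-fold lower. Of 13 androgen receptor targets and luminal markers, 4 rose, 6 fell and 3 were not called (camera adjusted p = 0.832), with NDRG1 1.74-fold higher and STEAP4 3.55-fold lower. Of 12 prostate basal markers, 5 rose, 6 fell and 1 was not called (camera adjusted p = 0.871). In the prostate basal marker list, KRT17 rose 11.4-fold, while TP63, which encodes the basal cell transcription factor p63, was 3.66-fold lower. Of 14 integrin genes, 5 rose, 5 fell and 4 were not called (camera adjusted p = 0.878), with ITGB3 4.59-fold higher and ITGB4 2.09-fold lower. Of 17 collagen genes, 8 rose, 6 fell and 3 were not called (camera adjusted p = 0.827), and COL12A1 rose 3.32-fold while COL5A2 was 3.21-fold lower. Of 18 genes of matrix metalloproteinases and the plasminogen system, 8 rose, 7 fell and 3 were not called, 9 and 8 adjusted over the list alone (camera adjusted p = 0.815). MMP9 rose 31.8-fold from a low level, 0.157 ± 0.0672 to 4.99 ± 0.627 (SD, n = 3 each), SERPINB2 rose 5.42-fold, and SERPINE2 was 1.80-fold lower. Of 8 Wnt pathway target genes, 4 rose, 2 fell and 2 were not called (camera adjusted p = 0.712), with DKK1 1.68-fold higher and TCF7 1.69-fold lower.

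Amino acid stress-response genes were mostly lower. Of 31 genes of the ATF4 amino acid response, 25 fell, 3 rose and 3 were not called, with a median log2 fold change of -0.43 (camera adjusted p = 6.01e-10; adjusted p = 0.0237 with an estimated correlation). CTH, which encodes the cysteine-producing enzyme cystathionine gamma-lyase, was 3.04-fold lower, at 34.7 ± 2.45 against 11.4 ± 0.438 (SD, n = 3 each). CHAC1, a glutathione-degrading enzyme gene, was 2.51-fold lower, and SLC7A11, the cystine transporter gene, was 2.21-fold lower, whereas PPP1R15A rose 1.49-fold. Of 22 NRF2 antioxidant genes, 12 fell, 7 rose and 3 were not called (median log2 fold change -0.20, camera adjusted p = 0.0103; adjusted p = 0.315 with an estimated correlation). The aldo-keto reductase genes AKR1B10 and AKR1C2 were 5.39-fold and 4.43-fold lower, and TXN, which encodes thioredoxin, rose 1.37-fold. Of 24 genes of endoplasmic reticulum chaperones and the unfolded protein response, 11 rose, 5 fell and 8 were not called (camera adjusted p = 0.878), with DERL2 1.42-fold higher and HYOU1 1.51-fold lower. Of 16 cytosolic heat shock protein genes, 8 rose, 5 fell and 3 were not called (camera adjusted p = 0.762), with DNAJA1 1.53-fold higher and HSPB1 1.30-fold lower.

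Cholesterol, glycolysis and hypoxia-related genes were mostly higher. Of 23 cholesterol synthesis genes, 19 rose, 2 fell and 2 were not called, with a median log2 fold change of 0.47 (camera adjusted p = 2.42e-06; adjusted p = 0.0386 with an estimated correlation). The sterol transfer gene STARD4 rose 2.42-fold, from 9.61 ± 0.314 to 23.3 ± 1.18 (SD, n = 3 each), and INSIG1 and IDI1 rose 1.87-fold and 1.82-fold, while SREBF2, which encodes a transcription factor of this pathway, was 1.28-fold lower. Of 21 targets of hypoxia-inducible factor, 17 rose, 3 fell and 1 was not called (median log2 fold change 0.51, camera adjusted p = 1.11e-05; adjusted p = 0.0505 with an estimated correlation). STC1 rose 4.01-fold, the carbonic anhydrase gene CA9 2.51-fold and the collagen-modifying enzyme gene PLOD2 2.14-fold, and CA12 was 1.68-fold lower. Of 18 glycolysis genes, 14 rose, 2 fell and 2 were not called (median log2 fold change 0.35, camera adjusted p = 0.000132; adjusted p = 0.216 with an estimated correlation). PFKFB4 and the glucose transporter gene SLC2A1 rose 2.60-fold and 2.18-fold, and the hexokinase gene HK2 was 1.18-fold lower. Of 14 fatty acid synthesis genes, 5 rose, 6 fell and 3 were not called (camera adjusted p = 0.815), with ELOVL6 1.32-fold higher and FASN 1.29-fold lower.

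Mitochondrially encoded genes were lower. Of 13, 11 fell, 1 rose and 1 was not called, with a median log2 fold change of -0.32 (camera adjusted p = 0.000132; adjusted p = 0.315 with an estimated correlation). The complex I genes MT-ND6 and MT-ND5 were 1.43-fold and 1.41-fold lower, and MT-ND1 rose 1.12-fold. The share of all listed signal in mitochondrially encoded genes was 5.57%, 5.65% and 5.53% in the control libraries and 4.55%, 4.51% and 4.78% in the knockdown libraries. Of 52 nuclear-encoded subunits of oxidative phosphorylation, 16 fell, 7 rose and 29 were not called (camera adjusted p = 0.371), with ATP5MC1 1.43-fold lower and NDUFC2 1.16-fold higher.

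Feedback genes of the MAPK pathway were mostly lower. Of 15, 11 fell, 2 rose and 2 were not called, with a median log2 fold change of -0.43 (camera adjusted p = 0.000105; adjusted p = 0.0696 with an estimated correlation). The phosphatase gene DUSP5 was 3.49-fold lower, at 108 ± 3.36 against 31.0 ± 0.743 (SD, n = 3 each), SPRY4, which encodes an inhibitor of receptor tyrosine kinase signalling, was 1.84-fold lower and EMP1 was 1.72-fold lower, while IER3 rose 1.45-fold. Of 16 immediate early genes, 4 rose, 8 fell and 4 were not called, 6 and 8 adjusted over the list alone (camera adjusted p = 0.708). MYC was 2.36-fold lower, at 575 ± 6.74 against 243 ± 10.3 (SD, n = 3 each), FOS was 2.60-fold lower and KLF6 rose 1.61-fold. Of 44 ribosome biogenesis genes and MYC targets, 17 rose, 12 fell and 15 were not called, 17 and 13 adjusted over the list alone (camera adjusted p = 0.966), with ODC1 1.45-fold and NOP56 1.28-fold higher and NPM3 1.38-fold lower. Of 82 ribosomal protein genes, 29 rose, 11 fell and 42 were not called, 25 and 11 adjusted over the list alone (camera adjusted p = 0.578), with RPL22L1 1.34-fold higher and RPL3 1.14-fold lower. Of 31 proteasome subunit genes, 27 rose, none fell and 4 were not called (median log2 fold change 0.26, camera adjusted p = 1.10e-07; adjusted p = 0.216 with an estimated correlation). PSMD2 and PSMC3 rose 1.51-fold and 1.47-fold. Of 34 lysosome and autophagy genes, 12 rose, 7 fell and 15 were not called (camera adjusted p = 0.871), with NEU1 1.44-fold higher and the cathepsin gene CTSD 1.51-fold lower.

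Markers of other cell types were nearly absent from the listed genes. Of 14 leukocyte markers, 1 was listed, the macrophage-associated CD68, at 26.3 ± 0.603 in control and 26.4 ± 0.720 in knockdown cells (SD, n = 3 each; limma adjusted p = 0.938). Of 10 fibroblast markers, 1 was listed, COL1A1, at 24.4 ± 0.900 and 24.7 ± 4.05 (SD, n = 3 each; limma adjusted p = 0.951). Of 10 endothelial markers, 1 was listed, PECAM1, which was 2.33-fold lower, at 54.2 ± 1.14 against 23.3 ± 0.695 (SD, n = 3 each; limma adjusted p = 1.59e-11). Of 19 neuroendocrine markers, 1 was listed, ENO2, which also encodes a glycolytic enzyme and rose 1.86-fold.

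Of the 42 tested lists, 13 were called higher and 4 lower at the preset correlation. With an estimated correlation, 5 were called higher and 1 lower: interferon-stimulated, NF-kB, DNA replication, mesenchymal and cholesterol genes higher, and ATF4 genes lower. The 25 lists not called had adjusted p-values between 0.371 and 0.966. Counts adjusted over the list alone were the same as those over all genes in 35 of the 46 lists, and the other 11 are given above. Median, mean and test direction differed in sign for 11 lists, none of them called, namely those of CDK inhibitors, p53 targets, growth-suppressing genes, Polycomb enzymes, epithelial genes, luminal markers, basal markers, integrins, collagens, histones and zinc finger genes.

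**Figure D3:**
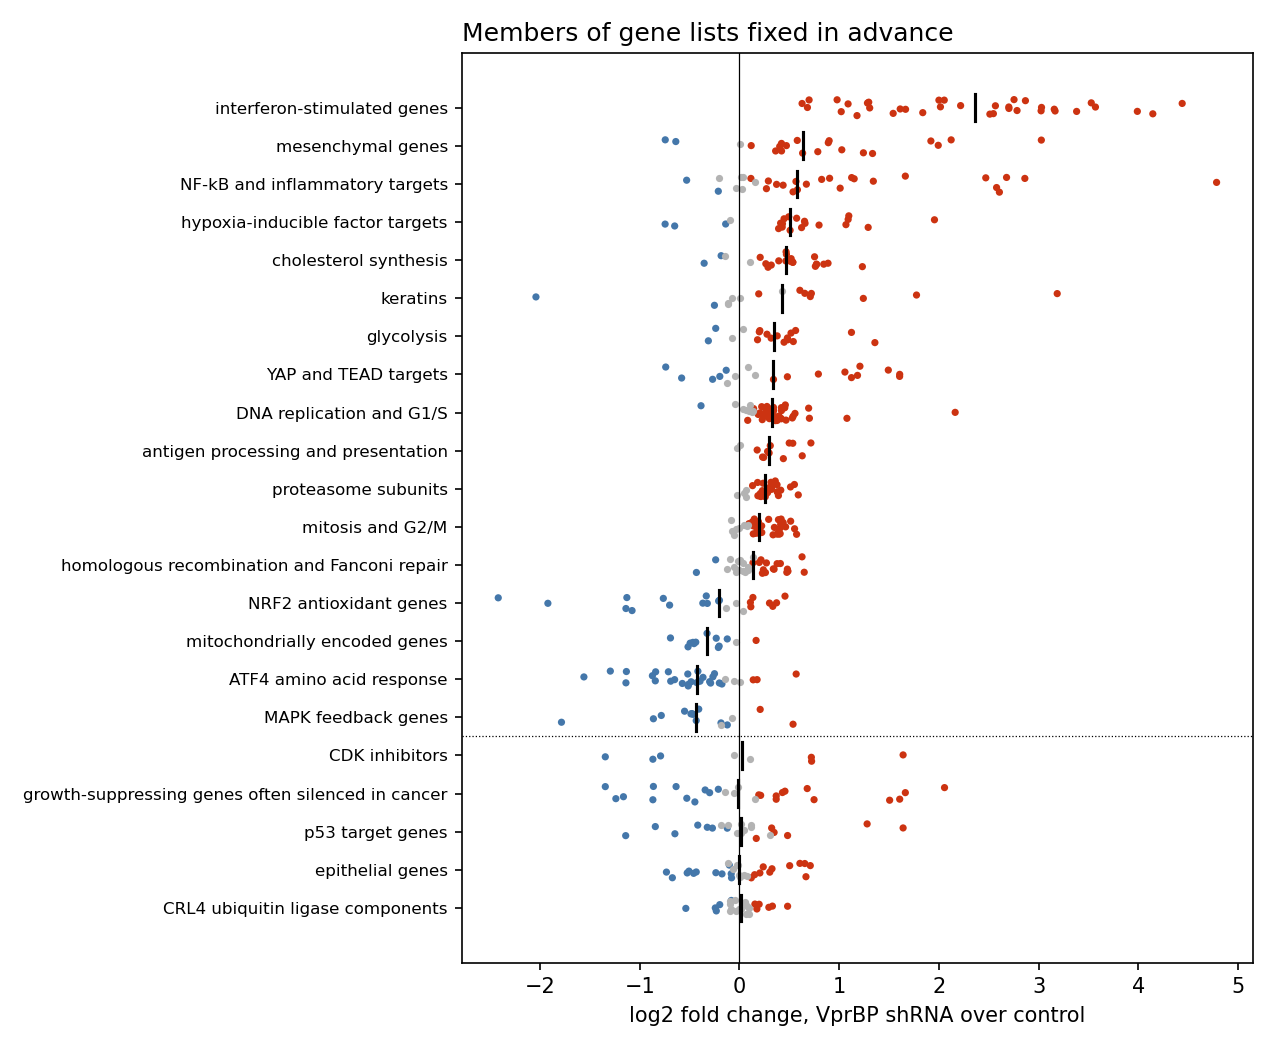
Log2 fold change (VprBP shRNA over control, 3 libraries each) of the listed members of the 17 called gene lists, above the dotted line, and of 5 lists that were not called, below it. Each point is a gene, red if called higher, blue if called lower and grey if not called, and the black bar is the list's median; the median is 2.36 for interferon-stimulated genes and -0.43 for ATF4 genes.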

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

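The pseudocounts of 0.1 and 1 were chosen after the data had been seen; the other alternatives were planned. DCAF1 was lower under every alternative run, and its log2 fold change lay between -0.95 and -0.99 with 1 library left out. The count of 7441 called genes fell to 651 (296 higher, 355 lower) when tested against a fold of 1.5 and to 454 (226 higher, 228 lower) with a 2-fold minimum, because most called differences are smaller than that. It was 6059 at an adjusted p under 0.01. With 1 library left out, 6697 to 7405 genes were called, 3643 to 4017 higher and 3054 to 3388 lower. Without knockdown replicate 3, which lay farthest from its group, 7405 were called, and 6997 of them were among the 7441. Median-ratio scaling called 7440 genes, 3723 higher and 3717 lower, and moved the median log2 fold change of all genes from 0.02 to 0.00. Library-size scaling called 7432, a mean of at least 5 called 7138, limma-voom called 7540, and pseudocounts of 0.1 and 1 called 7436 and 7445.

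A replicate block called 7042 genes (3826 higher, 3216 lower), 7024 of them shared. The numbers were not taken as pairs in the reported fit because the labels do not say what they stand for. Same-numbered libraries also did not deviate together: the correlations of their deviations from the group means were 0.02, -0.16 and -0.17. Not every library correlated best with the library of its own number.

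With a correlation estimated per list, 6 lists were called in place of 17. The number was 16 to 17 with 1 library left out and 17 under the other alternatives. With an estimated correlation, 11 of the called lists lost the call. For antigen processing (-0.011), hypoxia-inducible factor targets (0.0072) and MAPK feedback genes (0.0091) that correlation was below the preset 0.01. A higher correlation therefore cannot account for these losses. The remaining lists that lost the call had estimates between 0.0148 and 0.279. Their losses cannot be put down to the correlation alone either, because p also rose where the estimate was below the preset. The unadjusted camera p rose from 5.46e-10 to 0.00169 for DNA replication genes (estimate -0.0081). For ATF4 genes (estimate -0.0191) it rose from 2.86e-11 to 0.00162. Each of the 17 called lists kept its direction under the 15 alternatives run for lists, which leave out the fold minimums and the adjusted p under 0.01. Among the 228 genes selected by the naming rule, 20 results lost their call and none reversed under the scaling, filter, block, voom, pseudocount and left-out-library alternatives; the fold minimums and the stricter adjusted p were applied to the counts only. A gene or list called neither way was given no direction. The genes concerned were CASP9, RPS29, FANCM, HILPDA, HLA-F, H2BC4 and H2BC5, which are included in the counts of called members of their lists. The planned DESeq2 Wald test was not run because the values are not counts, and an unfiltered gene set was not run as an alternative because the reported fit has no filter. Genes under 150 estimated reads in every library are not listed, so loss or gain of rarer transcripts was not detectable here.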

Other observations

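The gene families in the first 2 paragraphs, the comparison of splits of the libraries and the comparison of the levels kept by MUC6, MUC5AC and MUC5B were chosen after the values had been seen.

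Within the list of interferon-stimulated genes described above, the transcription factor genes IRF9 and STAT2 rose 7.61-fold and 1.63-fold. Of 9 listed nucleic acid sensors and adaptors, 6 rose and 2 fell, with TBK1 not called. The RNA sensor genes RIGI and IFIH1, which belong to the same list, rose 6.10-fold and 3.14-fold, and EIF2AK2, which encodes the RNA-activated kinase PKR, rose from 82.4 ± 5.33 to 171 ± 7.68 (SD, n = 3 each). STING1, the adaptor of the DNA sensor cGAS, was 1.49-fold lower. Of 4 guanylate-binding protein genes, 3 rose, GBP1 by 4.83-fold, while GBP2 was not called (adjusted p = 0.0576 in limma) and was called lower under median-ratio and library-size scaling. Of 6 interferon receptor genes, 2 rose, 1 fell (IFNGR2, 1.49-fold lower) and the remaining members were not called. The number of interferon genes among the listed genes was 0, which sets no limit on their expression below 150 estimated reads per library.

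All 3 listed metallothionein genes rose, MT2A 17.3-fold, MT1X 9.62-fold and MT1F 5.56-fold, with the caution that these genes are close copies. Of 8 mucins and mucin-associated genes, 7 were lower and 1 higher. Besides FCGBP, DMBT1, MUC5AC and MUC5B, these were MUC6 (4.32 ± 0.946 against 0.102 ± 0.0843, SD, n = 3 each), TFF1 (3.18-fold lower) and AGR2 (1.09-fold lower), while the transmembrane mucin gene MUC1 was 1.66-fold higher. All 5 listed genes of the aldo-keto reductase subfamilies AKR1B and AKR1C were lower, from 5.39-fold for AKR1B10 to 2.17-fold for AKR1C1. Other aldo-keto reductases were not examined. Of 7 nuclear pseudogenes of mitochondrial genes, 6 were lower, MTATP6P1 by 1.43-fold, and these share sequence with the mitochondrial genes. Apart from GBP2, no listed member of these families changed its call under either other scaling.

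Most of the listed genes (60.9%) were called, most with small differences. The labelled split of the 6 libraries gave 7441 calls and the highest count among the other splits was 0. The labelled split was thus the only one (1) of 10 with as many calls, and 10 splits are too few for a share under 0.05. Every other split mixed control and knockdown libraries in both groups, so any large difference between the labelled groups keeps its count low. The comparison therefore says nothing about the cause of that difference. Calls stayed at 7330 after a smooth trend on gene span was removed, at 7301 after a trend on transcript GC content was removed, and at 7136 after the median of 51 neighbouring genes was subtracted. Span bias, GC bias and broad copy-number differences therefore cannot account for most calls. A difference between cultures or preparations that coincides with the groups stays open and may contribute, as does a response to VprBP depletion.

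For the interferon-stimulated genes, the scaling of the libraries is argued against, since their median log2 fold change was 2.34 or more under the other scalings. RNA from leukocytes cannot be told apart from a response of the PC3 cells, because 1 of 14 leukocyte markers was listed, and the number of leukocyte markers past the threshold and higher was 0. An innate response to the hairpin itself, a known effect of some double-stranded RNAs, may also have raised these genes. The list's median log2 value lay between 5.66 and 5.80 in the knockdown libraries (range 0.145) and between 3.15 and 3.35 in the control libraries, but the labels do not identify the hairpins, so this cannot be told apart from an effect of VprBP loss. The control cells also carried shRNA. Whether the knockdown libraries hold independent hairpins is not given in the labels, and a rescue was not analysed here.

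For the gel-forming mucins, a loss of the chromosome 11 region that reaches beyond the mucin genes is argued against by the 20 listed genes flanking MUC5AC and MUC5B, whose median log2 fold change was -0.091, with 8 lower and 3 higher. The lowest of the 20, at -2.99, was the adjacent MUC6, which kept 2.36% (SD 2.02) of its control level on 1, 6 and 2 estimated reads in the knockdown libraries, 5.17 percentage points below MUC5B (combined SD 2.32). MUC5AC and MUC5B kept 6.26% and 7.53%, a difference of 1.27 percentage points (combined SD 1.20), and 0 other genes from MUC6 to MUC5B were listed, so with MUC6 this near the floor a loss limited to that stretch cannot be told apart from lower expression. Scaling is argued against, since neither other scaling brought MUC5B nearer to 0 than its -3.73 in the main fit, and the nearer of them gave -3.75. A clonal difference between the control and knockdown cells and a response to VprBP depletion stay open and were not tested.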
